A study of Mus musculus with 15 samples.

How the data were processed

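RNA was sequenced from mouse cardiac endothelial cells in 5 groups with 3 labelled replicates each. The groups were untransduced cells in normoxia, untransduced cells in hypoxia, and 3 groups of lentivirus-treated cells in hypoxia. Of these 3, one carried GFP as infection control, one overexpressed Kdm4d, a demethylase of histone H3 lysine 9 (H3K9), and one carried a short hairpin RNA against Suv39h1, an H3K9 methyltransferase. Per the labels, cells were taken from hearts with beads against CD31, an endothelial surface protein also found on some leukocytes. The protocols describe neonatal hearts, 5 per well of a plate, and say that adult cells were used in animals; whether the untransduced libraries came from neonates is not given in the sources used here. Also not given are the oxygen level, the length of hypoxia and what a replicate number stands for. The labels name a pair of RNA extraction kits, one of them for the lentivirus-treated cells, so kit and transduction are confounded if each group followed its protocol.

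The authors deposited a table of raw counts for 55492 gene symbols in 15 libraries. Per the submitters' processing notes, reads were checked with FastQC, mapped to the mm10 mouse genome with STAR, counted per gene with featureCounts and compared with DESeq2; versions are not given. Libraries were made with a kit that keeps no strand, so a count can include reads of an overlapping gene on the other strand. In the table every gene of hypoxia replicate 2 was at 0. That library was left out, and 14 libraries were used where the plan had named 15. The hypoxia group therefore had 2 libraries and the other groups 3.

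Total counts of the 14 libraries ran from 10985825 to 13780670. CPM, counts scaled to a common library total, used totals adjusted by the trimmed mean of M values (TMM). Genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15), which left 15222 genes. Each contrast was tested in 1 edgeR 4.0.16 quasi-likelihood fit of all 14 libraries with the group as the term and robust estimation, in R 4.3.3. P values were adjusted over the genes tested by the Benjamini-Hochberg method, and genes at an adjusted p under 0.05 were called changed. The standard error of a log2 fold change was its size divided by the square root of the F statistic. The p values of single genes measure spread between libraries, and pooled or repeated cultures may vary less than independent animals.

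The labels number the replicates alike in each group, and pairing was checked by correlating the deviations of same-numbered libraries from their group means across genes. The correlations were 0.66 to 0.85 between Kdm4d and GFP, 0.60 to 0.84 between Suv39h1 knockdown and GFP, and 0.57 to 0.79 between Kdm4d and Suv39h1 knockdown, in 3 pairs each. Deviations cancel out within a group, so a shift shared by the libraries of 1 number also raises the correlations of the others. The 3 pairs are therefore not separate evidence of pairing. With every value over the set minimum of 0.1 in at least 3 pairs, a second fit with the replicate number as a block (paired fit) stands beside these 3 contrasts where it changed a call. Contrasts with untransduced hypoxia had 2 pairs, with correlations of 0.01 and 0.31 for normoxia and of 0.24 and 0.65 for GFP. Their fit with the block is given with the alternatives.

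Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, with the Benjamini-Hochberg method over the 28 lists of a contrast. At the preset value camera weighs the genes of a list against all other genes. Its p can therefore be far smaller than the spread between libraries alone would give. An estimated correlation and fry, a rotation test, were run beside it. The lists were H3K9 methylation machinery, hypoxia response, glycolysis, oxidative phosphorylation, endothelial identity, angiogenesis and Notch, cell junction and adhesion, mesenchymal transition, interferon response, inflammation, cell cycle, p53 targets, stress and unfolded protein, immediate early genes, cholesterol synthesis, extracellular matrix, germline genes silenced by H3K9 methylation, zinc finger clusters, clustered protocadherins, imprinted genes and cytosolic ribosomal proteins, together with markers of fibroblasts, mural cells, cardiomyocytes, leukocytes, erythroid cells, mesothelium and lymphatic endothelium. Named genes followed a rule. It took Suv39h1, Kdm4d and changed members of the H3K9 list. It took the 10 largest rises and falls among changed genes with a mean of at least 5 CPM in the higher group, no overlap between the groups' libraries and a regular gene symbol. It also took up to 2 risen and 2 fallen members of each list by smallest p.

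Groups, contrasts, tests, lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were DESeq2 size factors in edgeR, DESeq2 1.42.0, no filter on low counts, a stricter filter of 1 CPM in 3 libraries, a fit on the libraries of a contrast alone, the replicate block, an absolute log2 fold change of at least 1, and leaving out each library in turn. Alternatives for the paired counts, leaving out the libraries numbered 2, leaving out leukocyte-associated genes, and those for the overlaps with the GFP contrast were added after the data were seen. Overlaps of called genes were compared with n1 × n2 / N and Fisher's exact test, 2-sided. That test counts genes, which are not independent replicates. Where contrasts share the GFP libraries, 20 simulated sets of unchanged groups gave the correlation that sharing alone produces.

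The fits were tested on simulated data with the spread of these libraries and 200 changed genes, in 3 draws. Means and spread came from the fit with the replicate block, so replicate differences were alike in each group, as the paired fit assumes. In the measured libraries they varied. The median difference of endothelial identity genes in number 2 libraries ran from −1.25 to −0.09 between groups. The paired shares below may therefore be too favorable. For Kdm4d against GFP, 20.7% of 2-fold and 59% of 4-fold changes were found (paired, 59% and 84.3%). For Suv39h1 knockdown the shares were 18.7% and 63.3% (paired, 60.3% and 86.7%), and for hypoxia 9.3% and 56.3%. False calls made up 0% of unpaired calls and at most 6.2% of paired ones. Gene positions and lengths came from GENCODE vM21 (GRCm38, the same assembly as mm10), which held 14962 of the genes tested (98.3%). Lengths and GC content entered a loess correction with a span of 0.3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, on log2 CPM with a pseudocount of 1 where libraries are compared.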

Results

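Gene expression was measured by RNA sequencing in mouse cardiac endothelial cells kept in normoxia or hypoxia, with and without lentiviral changes to a pair of genes that act on methylation of histone H3 lysine 9 (H3K9). Counts were available for 3 normoxia libraries, 2 untransduced hypoxia libraries and 3 libraries each of the GFP, Kdm4d and Suv39h1 knockdown groups in hypoxia. Total counts were 13106403, 11407232 and 13698771 in normoxia and 12778501 and 12865807 in hypoxia. They were 13507609, 12322982 and 13414494 with GFP, 12396013, 13780670 and 11571314 with Kdm4d, and 13546130, 11164758 and 10985825 with Suv39h1 knockdown. The mitochondrial share of counts was 1.44% to 1.68% in normoxia and 0.39% to 1.21% in the hypoxic libraries, and the 10 most abundant genes of a library took 5.15% to 7.93%.

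The libraries numbered 2 stood apart from those numbered 1 and 3 in each group that had one. On the first principal component (35.9% of the variance) they lay at 33.87 to 51.05, and the other libraries at −32.67 to 7.66. Markers of inflammation were higher in them (median log2 difference from numbers 1 and 3 of 1.01 over 28 genes), as were cytosolic ribosomal protein genes (0.91, 81 genes) and hypoxia response genes (0.69, 35 genes). Endothelial identity genes (−0.93, 32 genes) and lymphatic endothelial markers (−1.78, 5 genes) were lower. The second component (26% of the variance) parted normoxia (−65.28 to −39.53) from all hypoxic libraries (6.91 to 17.76). Because the hypoxia group had no usable library numbered 2, the contrasts with it were unbalanced for this difference.

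**Figure D1:**
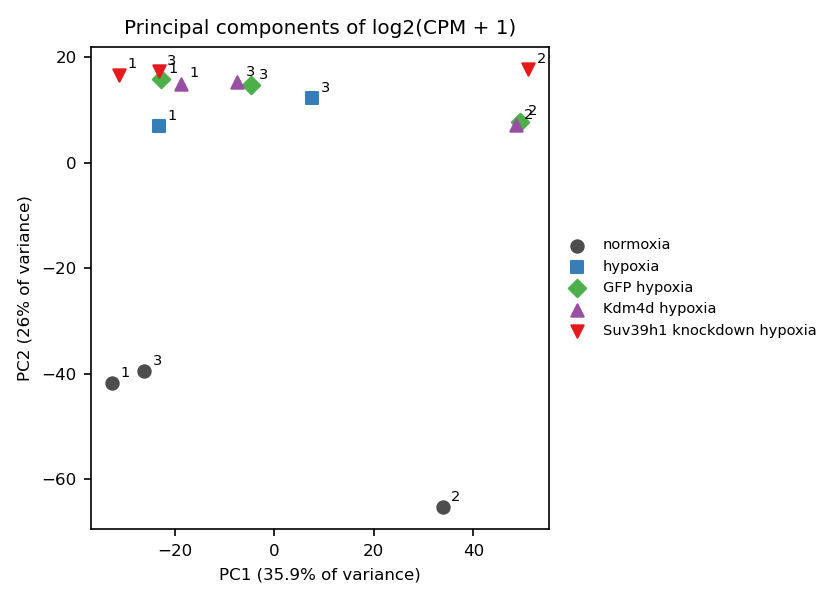
Each point is 1 of the 14 libraries on the first and second principal components of log2 CPM, with its replicate number beside it and its group as symbol and color. The libraries numbered 2 lie at the right (33.87 to 51.05), and normoxia lies low on the second component (−65.28 to −39.53).

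The targeted genes were examined first, as a check of the labels. Suv39h1 stood at 5.85, 5.07 and 4.73 CPM in the knockdown libraries (80, 56 and 54 counts) and at 14.9, 13.6 and 22.1 CPM in the GFP libraries (201, 166 and 289 counts). The log2 fold change was −1.69 ± 0.43 (SE, n = 3 and 3), a 3.22-fold lower level, with an edgeR quasi-likelihood adjusted p of 0.387 and an unadjusted p of 0.00191. In the paired fit it was −1.68 ± 0.42 (adjusted p = 0.0823, edgeR). Suv39h1 was at 17.4, 20.5 and 15.6 CPM in normoxia, 13.5 and 21.2 CPM in hypoxia, and had 334, 79 and 172 counts with Kdm4d, where the second library (5.98 CPM) lay near the knockdown level. The gene (ENSMUSG00000039231.18, chromosome X, 8061171 to 8074760, minus strand, mm10) overlaps the antisense gene Gm14820, so its unstranded counts are uncertain. The hairpin's target CGAGTCCGTATTGAATGCAAA matched the coding sequence in exon 6 of 6 at 8062886 to 8062906. Kdm4d (ENSMUSG00000053914.9, chromosome 9, 14462548 to 14500482, minus strand) stood at 76.6, 25.9 and 11.7 CPM with the Kdm4d virus (944, 342 and 134 counts). With GFP it had 6, 1 and 2 counts (0.44, 0.08 and 0.15 CPM), and the log2 fold change was 7.31 ± 0.84 (edgeR adjusted p = 0.00803, n = 3 and 3). The cloned coding sequence lay in exon 2 of 2 (14463028 to 14464560), so virus and native transcripts were not told apart.

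**Figure D2:**
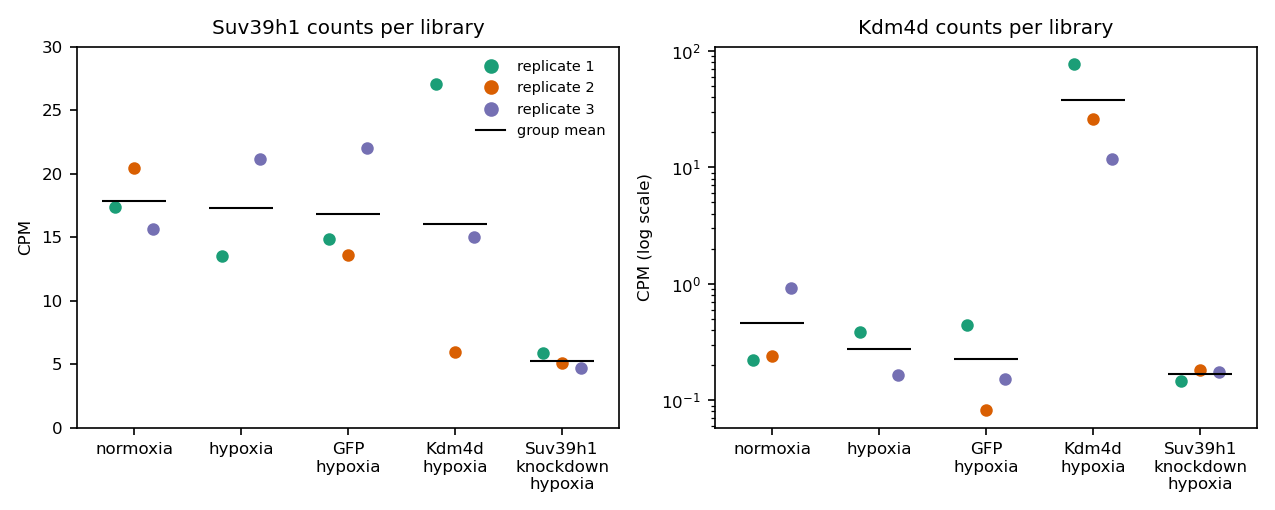
CPM of Suv39h1 (linear axis) and Kdm4d (log axis) in each library, with points colored by replicate number and bars at the group means. Suv39h1 lies at 4.73 to 5.85 CPM in the knockdown libraries, and Kdm4d at 11.7 to 76.6 CPM in the Kdm4d libraries.

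The comparison of hypoxia with normoxia was made in untransduced cells (n = 2 and 3). The mitochondrial share of counts differed as well (1.68%, 1.64% and 1.44% in normoxia, 1.14% and 0.52% in hypoxia), so a difference in RNA quality between these groups is not excluded. Among the genes that rose were some of the response to low oxygen and of glycolysis. Ankrd37, a target of hypoxia-inducible factors, went from 2.40 ± 1.09 to 30.3 ± 0.568 CPM (mean ± SD), a log2 fold change of 3.66 ± 0.49 (SE; adjusted p = 0.00815, edgeR quasi-likelihood with Benjamini-Hochberg). Hif3a, itself a hypoxia-inducible factor subunit, rose by 1.69 ± 0.18 (53.4 ± 11.2 to 173 ± 22.9 CPM). The H3K9 demethylase Kdm3a rose by 1.25 ± 0.22, and the glycolytic genes Aldoc (an aldolase) and Pfkl (a phosphofructokinase) by 3.58 ± 0.60 and 1.54 ± 0.25. Gipr, a receptor for an incretin hormone, rose from 0.755 ± 0.601 to 75.1 ± 0.640 CPM (6.63 ± 0.97), Selenbp1 by 4.83 ± 0.80 and Fam107a by 4.27 ± 0.58. Among the falls were the cytokine Il6 (42.4 ± 18.2 to 5.02 ± 2.35 CPM, −3.07 ± 0.53), the chemokine Ccl6 (−3.64 ± 0.72), the adhesion molecule Selp (−1.25 ± 0.27) and the contractile genes Tagln (−1.35 ± 0.25) and Cnn1 (−1.78 ± 0.36). The edgeR adjusted p of these genes lay between 0.00214 (Hif3a) and 0.0432 (Selp). Counts of Ankrd37, Hif3a, Ccl6, Selp and Tagln may include an overlapping gene on the other strand.

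Of the 15222 genes tested, 326 changed with hypoxia (203 up and 123 down, edgeR quasi-likelihood). Of 35 hypoxia response genes, 10 rose, 0 fell and 25 did not pass (26 up when adjusted over the list alone); the median log2 fold change was 1.40 (camera adjusted p = 3.46e-17, adjusted p = 0.525 with an estimated correlation). Of 18 glycolysis genes, 5 rose, 0 fell and 13 did not pass (16 up adjusted over the list alone; median 1.20, camera adjusted p = 2.98e-13, adjusted p = 0.707 with an estimated correlation). Of 48 oxidative phosphorylation genes, 0 rose, 2 fell and 46 did not pass (4 down adjusted over the list alone; median −0.44, camera adjusted p = 6.87e-12, adjusted p = 0.707 with an estimated correlation). The 2 were Cycs (−0.84 ± 0.15) and Cyc1 (−0.71 ± 0.16), the electron carrier and its partner in the respiratory chain. Of 37 cell cycle genes, 0 passed either way (0 adjusted over the list alone; median −0.55, camera adjusted p = 1.61e-05, adjusted p = 0.707 with an estimated correlation). None of the 28 lists passed with an estimated correlation, while 9 passed camera at its preset value and 1, hypoxia response, passed fry (adjusted p = 0.019).

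Of 16 leukocyte markers, read here as a sign of other cells in the preparation, 0 rose with hypoxia, 1 fell and 15 did not pass (1 down adjusted over the list alone; median −0.76, camera adjusted p = 0.000834, adjusted p = 0.707 with an estimated correlation, fry adjusted p = 0.229). Of the 16, 14 had a lower mean in hypoxia, and Csf1r (17.8 and 20.5 CPM) and Laptm5 (32.6 and 34.5 CPM) had a higher one. The 1 was Lyz2, the lysozyme of macrophages, whose close copy Lyz1 may share reads with it (183 ± 41.9 to 68.7 ± 6.80 CPM, −1.42 ± 0.26, edgeR adjusted p = 0.0238). Without hypoxia replicate 1 the list's median was −0.48 (adjusted p = 0.0541). Of 35 interferon response genes, 0 passed (12 up adjusted over the list alone; median 0.95, camera adjusted p = 7.75e-07, adjusted p = 0.75 with an estimated correlation); without hypoxia replicate 3 the median was −0.04 (adjusted p = 0.388). Of 32 endothelial identity genes, 0 passed (0 adjusted over the list alone; median 0.46, camera adjusted p = 0.0357, adjusted p = 0.789 with an estimated correlation). That call was lost without normoxia replicate 1 (0.42, adjusted p = 0.0793), normoxia replicate 2 (0.33, adjusted p = 0.0753) or hypoxia replicate 1 (0.12, adjusted p = 0.245). Of 81 genes on the cytosolic ribosomal protein list, 0 rose and 1 fell (0 adjusted over the list alone). It was Rpl7l1, an Rpl7-like gene that entered the list by its symbol. The list's median was −0.28 (camera adjusted p = 0.0233, adjusted p = 0.886 with an estimated correlation). The median was 0.13 without normoxia replicate 2 (adjusted p = 0.731), 0.11 without the libraries numbered 2 (adjusted p = 0.431) and −0.05 without hypoxia replicate 1 (adjusted p = 0.919).

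Of the 28 lists 19 did not pass camera in this contrast. Of 21 genes of the H3K9 methylation machinery, 1 rose, Kdm3a (3 up adjusted over the list alone; median 0.12, camera adjusted p = 0.14). Of 19 genes of mesenchymal transition, 0 rose and 3 fell, Tagln and Cnn1 among them (1 up and 4 down adjusted over the list alone; median −0.16, camera adjusted p = 0.0786). Of 13 mural cell markers, 1 rose, the pericyte gene Rgs5 (2.22 ± 0.40), and 2 fell, again Tagln and Cnn1 (2 up and 3 down adjusted over the list alone; median −0.28 with a mean of 0.01, camera adjusted p = 0.479). Of 28 inflammation genes, 0 rose and 2 fell, Il6 and Selp (2 adjusted over the list alone; median −0.85, camera adjusted p = 0.1). Of 31 genes of cell junction and adhesion 1 rose, the laminin Lama4 (1.17 ± 0.18; 1 adjusted over the list alone; median 0.26, camera adjusted p = 0.0626). Angiogenesis and Notch (32 genes, 0 passing, median 0.25, adjusted p = 0.159), p53 targets (22 genes, 0 passing and 2 up adjusted over the list alone, median 0.03, adjusted p = 0.479), clustered protocadherins (39 genes, 0 passing, median 0.11, adjusted p = 0.698), germline genes silenced by H3K9 methylation (5 genes, 0 passing, median −0.13, adjusted p = 0.369) and erythroid markers (2 genes, 0 passing, median −0.46, adjusted p = 0.921) did not pass. Nor did markers of fibroblasts (16 genes, 0 passing, median −0.00 with a mean of 0.12, adjusted p = 0.433), cardiomyocytes (18 genes, 0 passing, median 0.02, adjusted p = 0.921), mesothelium (10 genes, 0 passing, median −0.36, adjusted p = 0.953) and lymphatic endothelium (5 genes, 0 passing, median 0.74, adjusted p = 0.21). The remaining lists were stress and unfolded protein (24 genes, 1 up and 1 down, median −0.26, adjusted p = 0.245), immediate early genes (19 genes, 0 passing, median 0.03 with a mean of −0.19, adjusted p = 0.799), cholesterol synthesis (22 genes, 0 passing, median 0.13, adjusted p = 0.479), extracellular matrix (25 genes, 1 up, Lama4, median 0.00 with a mean of 0.11, adjusted p = 0.228) and imprinted genes (17 genes, 2 up, median 0.41, adjusted p = 0.0626).

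The hypoxia result rested on few libraries. The count of 326 was 82, 118 and 118 without normoxia replicate 1, 2 or 3, and 165 and 29 without hypoxia replicate 1 or 3. It was 1111 with DESeq2, 179 with no filter, 34 in a fit of these libraries alone and 819 without those numbered 2. Of the 39 genes the naming rule gave, 26, 20 and 22 lost their call without normoxia replicate 1, 2 or 3, and 20 and 34 without hypoxia replicate 1 or 3. Gipr, Fam107a, Ankrd37 and Hif3a kept theirs without each library.

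The comparison of the GFP group with untransduced hypoxia covered infection and all else that differed between them (n = 3 and 2). Among the genes that fell were genes of macrophages. Lyz2 went from 68.7 ± 6.80 to 2.93 ± 0.905 CPM, a log2 fold change of −4.54 ± 0.28 (edgeR quasi-likelihood adjusted p = 1.9e-05). The complement genes C1qa and C1qc fell by 4.84 ± 0.61 and 5.04 ± 0.63 on the log2 scale, and Ptprc, the leukocyte surface protein CD45, by 4.62 ± 0.70 (5.28 ± 0.762 to 0.204 ± 0.157 CPM). The macrophage genes Adgre1 (−4.96 ± 0.86) and Mrc1 (−4.46 ± 0.60) fell alike. In all, 34 genes fell and 0 rose (edgeR; 373 genes at an unadjusted p under 0.05, and 85 genes changed with DESeq2). Of 16 leukocyte markers, 11 fell, 0 rose and 5 did not pass (14 down adjusted over the list alone; median −4.50, or −4.19 with Cd52, which had no counts with GFP, at its bound). Camera gave an adjusted p of 2.57e-59 (adjusted p = 0.00197 with an estimated correlation).

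Of the 28 lists 7 passed camera in this contrast, and leukocyte markers were the 1 that passed with an estimated correlation. Of 10 mesothelial markers, genes of the heart's outer lining, 0 passed (5 down adjusted over the list alone; median −1.27, camera adjusted p = 1.75e-05, adjusted p = 0.417 with an estimated correlation). Of 18 cardiomyocyte markers, 0 passed (median −0.77, camera adjusted p = 2.07e-09, adjusted p = 0.634 with an estimated correlation). Also passing camera were lymphatic endothelial markers (median −0.88), stress and unfolded protein (0.37) and cholesterol synthesis (0.30). With an estimated correlation their adjusted p was 0.796, 0.796 and 0.634. Without GFP replicate 2 the lymphatic (−0.50, camera adjusted p = 0.156) and stress (0.10, 0.0823) calls were lost. Without hypoxia replicate 1 the 3 medians were −1.38, 0.20 and 0.12, and without hypoxia replicate 3 the lymphatic median was −0.69. Those fits kept 1 hypoxia library, so medians alone are given and no kept call is claimed. Interferon response genes had a median of 0.43 (0 of 35 passing, camera adjusted p = 4.46e-11, adjusted p = 0.796 with an estimated correlation), which was −0.01 without hypoxia replicate 1 (adjusted p = 0.673). The GFP count of 34 was 6 and 5 without GFP replicate 1 or 2, 3 and 18 without hypoxia replicate 1 or 3, 7 without the libraries numbered 2 and 1 in a fit of these libraries alone. Of 10 named genes, 7, 8 and 2 lost their call without GFP replicate 1, 2 or 3, and 9 and 4 without hypoxia replicate 1 or 3; Lyz2 kept its call each time. The labels name another extraction kit for transduced cells and do not give the age of the animals behind the untransduced libraries.

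**Figure D3:**
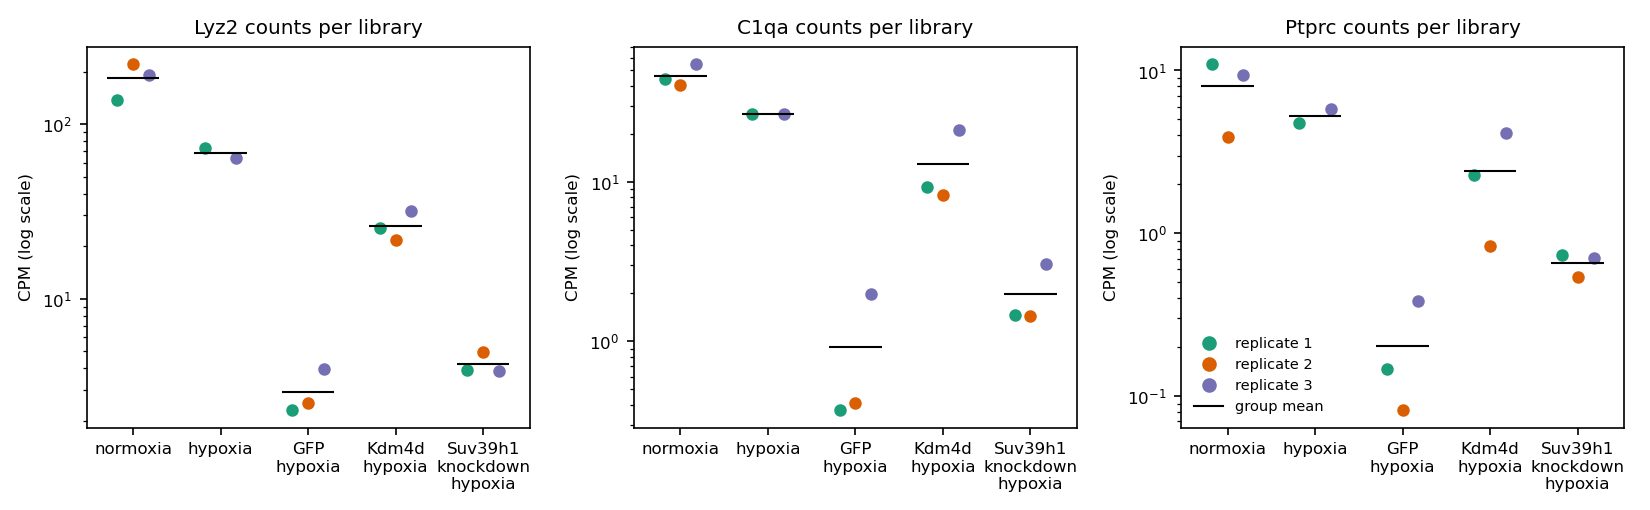
CPM of the leukocyte genes Lyz2, C1qa and Ptprc on log axes in each library, with points colored by replicate number and bars at the group means. Mean Lyz2 was 183 CPM in normoxia, 68.7 in hypoxia, 26.2 with Kdm4d, 4.24 with Suv39h1 knockdown and 2.93 with GFP; a library with no count is not drawn.

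The comparison of Kdm4d with GFP set Kdm4d overexpression in hypoxia against the infection control (n = 3 and 3). Besides Kdm4d itself, 3 genes of leukocytes rose in the unpaired fit. Lyz2 went from 2.93 ± 0.905 to 26.2 ± 5.04 CPM, a log2 fold change of 3.16 ± 0.26 (adjusted p = 0.000492, edgeR quasi-likelihood). Adam8, a protease of leukocytes whose counts may include the overlapping Gm16201, rose by 2.52 ± 0.30 (4.73 ± 1.59 to 27.1 ± 9.98 CPM, edgeR adjusted p = 0.00924). Ncf1, a part of the phagocyte oxidase named after its values were seen as the remaining call, rose by 3.55 ± 0.36 (edgeR adjusted p = 0.00306). These 4 genes rose and 0 fell in the unpaired edgeR fit (291 genes at an unadjusted p under 0.05; 51 genes changed with DESeq2). In the paired fit 34 genes rose and 0 fell, the 4 among them. They included C1qc (3.86 ± 0.42), C1qa (3.79 ± 0.37), C1qb (3.75 ± 0.42), Cd84 (3.35 ± 0.47), the scavenger receptor Msr1 (3.28 ± 0.54), Mrc1 (3.31 ± 0.54), Ccl6 (3.35 ± 0.55) and the lysosomal protease Ctss (2.99 ± 0.39), with paired edgeR adjusted p from 0.00112 to 0.0409.

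Of the 16 leukocyte markers, 1 rose with Kdm4d and 15 did not pass in the unpaired fit (13 up adjusted over the list alone; median 3.28, or 2.96 with Cd52 at its bound; camera adjusted p = 3.7e-52, adjusted p = 0.0034 with an estimated correlation). In the paired fit 11 rose and 5 did not pass (15 up adjusted over the list alone; median 3.23, camera adjusted p = 1.76e-38, adjusted p = 0.0322 with an estimated correlation). The Kdm4d means stayed below those of untransduced hypoxia for Lyz2 (26.2 and 68.7 CPM), C1qa (12.9 and 26.8 CPM) and Ptprc (2.40 and 5.28 CPM). Of 10 mesothelial markers, 0 passed (1 up adjusted over the list alone; median 1.09, camera adjusted p = 1.36e-05, adjusted p = 0.335 with an estimated correlation). Lymphatic endothelial markers passed camera in the paired fit alone (0 of 5 genes passing, median 0.49, camera adjusted p = 1.01e-06, adjusted p = 0.151 with an estimated correlation; unpaired camera adjusted p = 0.0725). So did fibroblast markers (0 of 16, paired median 0.20, adjusted p = 0.0419; unpaired 0.0776) and cholesterol synthesis (0 of 22, paired median −0.10, adjusted p = 0.0491; unpaired 0.063). With an estimated correlation the paired adjusted p was 0.826 for fibroblast markers and 0.842 for cholesterol synthesis.

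Hypoxia response genes showed no change past the threshold with Kdm4d (0 of 35, median 0.06, camera adjusted p = 0.341), and in the H3K9 machinery 1 of 21 genes rose, Kdm4d. The 6 other lists that passed camera unpaired had 0 genes passing and small medians: cardiomyocyte markers 0.31, stress and unfolded protein −0.22, interferon response −0.17, inflammation 0.18, oxidative phosphorylation −0.07 and ribosomal proteins −0.10 (camera adjusted p from 0.00109 to 0.0265, adjusted p from 0.855 to 0.939 with an estimated correlation). Each lost its call or turned without single libraries. Without GFP replicate 2 the medians were 0.13 for cardiomyocyte markers, 0.04 for stress, −0.06 for interferon, 0.05 for oxidative phosphorylation and 0.22 for ribosomal proteins, which then passed camera in the other direction (adjusted p = 0.0129). Without Kdm4d replicate 1 they were 0.19, −0.14, 0.01, −0.00 and 0.07 in that order. Without Kdm4d replicate 3 they were 0.18 for cardiomyocyte markers, −0.14 for stress, 0.00 for oxidative phosphorylation and 0.03 for ribosomal proteins, and without GFP replicate 3 −0.06 for interferon. Inflammation was at 0.01 without GFP replicate 1 and −0.50 without Kdm4d replicate 2. Leaving out a single library numbered 2 keeps its counterpart in the other group, so such unpaired values also carry the difference of those libraries. C3, a complement gene of the inflammation list, passed in the paired fit (1.20 ± 0.21, edgeR adjusted p = 0.0493). It lay 2.66 log2 units higher in the libraries numbered 2, and its unpaired log2 fold change was −0.01 without Kdm4d replicate 2.

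The Kdm4d count depended on single libraries. Unpaired, the 4 genes became 2 without GFP replicate 1 or 2, and 11 without GFP replicate 3 or Kdm4d replicate 2. Kdm4d lost its call without GFP replicate 1 (8.21, edgeR adjusted p = 0.0502) or 2 (6.95, 0.0747), as did Adam8 (2.37, 0.106 and 2.40, 0.0784). Lyz2 kept its call without each library. The paired 34 became 12, 10, 13 and 8 without GFP replicate 1, GFP replicate 2, Kdm4d replicate 1 or Kdm4d replicate 3, and 3 without all libraries numbered 2. Genes lowered in GFP against hypoxia in a fit with the replicate block were also left out. That set rests on the same GFP libraries, with 2 same-numbered pairs and a number 2 difference taken from the groups that had one. With it left out, 1 unpaired and 4 paired calls stayed.

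**Figure D4:**
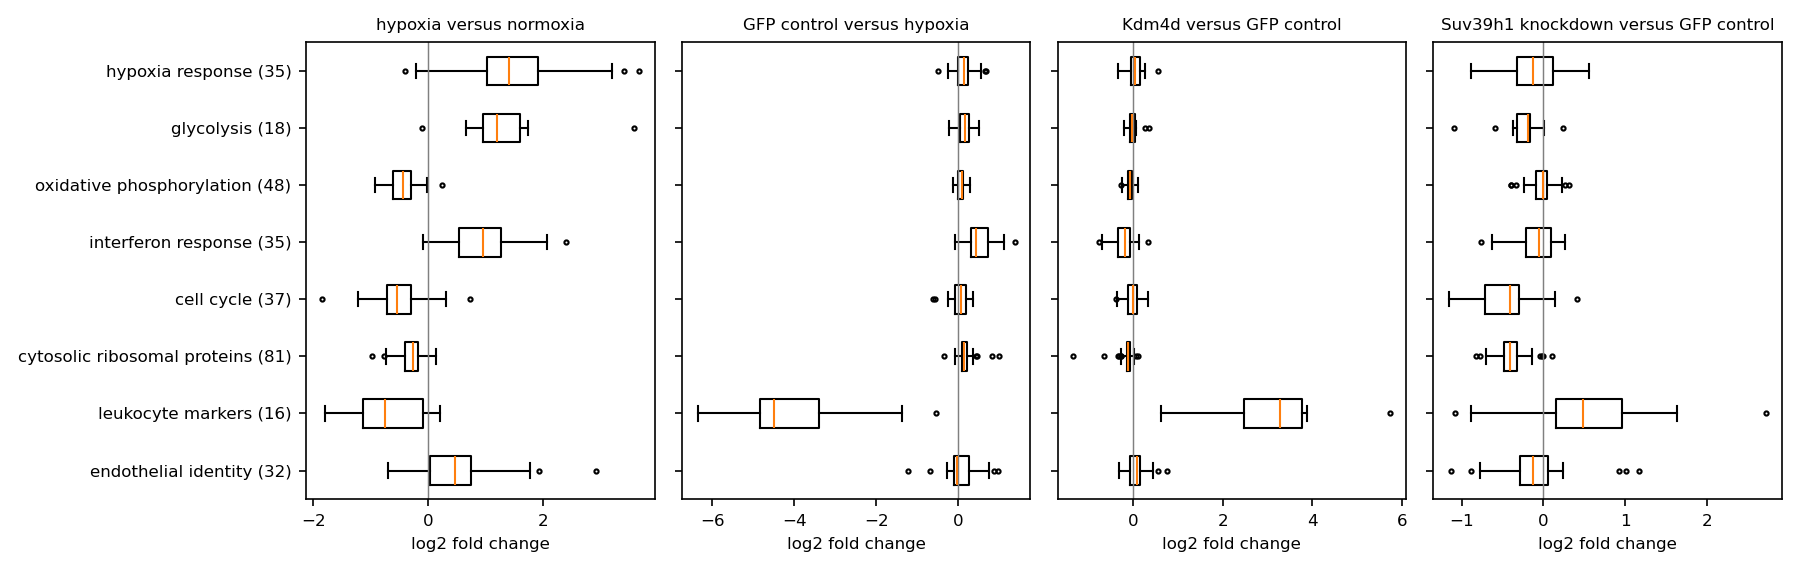
Log2 fold changes of the members of 8 gene lists (numbers of genes in parentheses) in 4 contrasts from the unpaired fit, as boxes of the quartiles and median with whiskers to 1.5 interquartile ranges and points beyond; the horizontal ranges differ between panels. Leukocyte markers have medians of −4.50 in GFP against hypoxia and 3.28 in Kdm4d against GFP.

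The comparison of Suv39h1 knockdown with GFP was made in hypoxia (n = 3 and 3). In the unpaired edgeR fit 0 genes changed, Suv39h1 included, with 881 genes at an unadjusted p under 0.05 and 81 genes changed with DESeq2. In the paired edgeR fit 57 genes rose and 139 fell. Tgfbr1, a receptor for transforming growth factor beta, rose from 75.6 ± 19.1 to 184 ± 61.1 CPM (1.27 ± 0.19, paired edgeR adjusted p = 0.0238). Il6ra, a receptor for interleukin 6, rose by 1.00 ± 0.22, and Trdn and Srl, genes of muscle calcium stores, by 1.03 ± 0.14 and 1.55 ± 0.33. Among the falls, Litaf, a gene of the endosome, went from 294 ± 33.4 to 118 ± 8.84 CPM (−1.32 ± 0.16, paired edgeR adjusted p = 0.0163) and the growth cone gene Gap43 fell by 1.91 ± 0.26. The cholesterol enzyme Msmo1 fell by 1.36 ± 0.28, the junctional adhesion molecule F11r by 1.05 ± 0.21, the argininosuccinate synthase Ass1 by 1.10 ± 0.20 and the laminins Lama4 and Lamc1 by 0.66 ± 0.13 and 0.62 ± 0.13 on the log2 scale. Ankrd37, which rose with hypoxia, fell by 0.83 ± 0.14, and the Notch receptor Notch1 by 0.50 ± 0.10. The paired edgeR adjusted p of these genes was 0.0163 to 0.0491, and none passed unpaired. Counts of Litaf, Trdn, Srl, Gap43, Il6ra, Lamc1, Notch1 and Ankrd37 may include overlapping genes.

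Gene lists were tested for Suv39h1 knockdown in both fits. Of 81 cytosolic ribosomal protein genes, 0 passed unpaired (0 adjusted over the list alone; median −0.41, camera adjusted p = 9.9e-10, adjusted p = 0.817 with an estimated correlation). Paired, 2 fell, Rpl28 and Rps9 (57 down adjusted over the list alone; median −0.44, camera adjusted p = 7.62e-27, adjusted p = 0.378 with an estimated correlation). Without GFP replicate 2, which keeps knockdown replicate 2, the unpaired median was −0.09 (adjusted p = 0.0536). Cell cycle genes had a median of −0.41 (0 of 37 passing, camera adjusted p = 1.6e-08, adjusted p = 0.817 with an estimated correlation). Cholesterol synthesis genes had a median of −0.39 (0 of 22 passing, camera adjusted p = 6.52e-09, adjusted p = 0.817 with an estimated correlation); paired, 1 fell, Msmo1, and 7 adjusted over the list alone. Cell cycle and cholesterol lists kept their calls without each library. Stress and unfolded protein genes had a median of −0.42 (0 of 24 passing, camera adjusted p = 2.38e-05, adjusted p = 0.817 with an estimated correlation), which was −0.09 without GFP replicate 2 (adjusted p = 0.0745). These 4 lists did not pass fry (unpaired adjusted p of 0.632 to 0.804). Ribosomal protein (0.91), stress (0.68) and cholesterol (0.27) genes were higher in the libraries numbered 2 than in the others, and without all of those libraries the 4 lists passed camera.

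Immediate early genes had a median of −0.43 with knockdown (0 of 19 passing, camera adjusted p = 0.00166, adjusted p = 0.817 with an estimated correlation) and lost their call without GFP replicate 2 (−0.13, adjusted p = 0.138) or knockdown replicate 1 (−0.15, adjusted p = 0.106). Extracellular matrix genes had a median of −0.22 (0 of 25 passing, camera adjusted p = 0.0102, adjusted p = 0.817 with an estimated correlation) and lost it without GFP replicate 1 (−0.21, adjusted p = 0.0626). Cardiomyocyte markers had a median of 0.61 (0 of 18 passing, camera adjusted p = 0.00379, adjusted p = 0.817 with an estimated correlation), 0.34 without GFP replicate 2 (adjusted p = 0.168) and 0.03 without knockdown replicate 1 (adjusted p = 0.877). The leukocyte markers had a median of 0.49, or 0.37 with Cd52 at its bound (0 of 16 passing, camera adjusted p = 0.0177, adjusted p = 0.817 with an estimated correlation). Their call was lost in the paired fit (0.50, adjusted p = 0.105), without GFP replicate 1 (0.09, adjusted p = 0.741) or without knockdown replicate 2 (0.26, adjusted p = 0.247). Inflammation genes had a median of −0.36 (0 of 28 passing, camera adjusted p = 0.0102, adjusted p = 0.817 with an estimated correlation), 0.26 without GFP replicate 2 (adjusted p = 0.449), 0.05 without knockdown replicate 1 (adjusted p = 0.491) and −0.11 without knockdown replicate 3 (adjusted p = 0.0592). Glycolysis genes had a median of −0.19 (0 of 18 passing, camera adjusted p = 0.00576, adjusted p = 0.835 with an estimated correlation), 0.06 without GFP replicate 2 (adjusted p = 0.37), −0.07 without knockdown replicate 1 (adjusted p = 0.0672) and 0.04 without knockdown replicate 3 (adjusted p = 0.726). Fibroblast markers had a median of −0.19 (0 of 16 passing, camera adjusted p = 0.0203, adjusted p = 0.817 with an estimated correlation), −0.24 without GFP replicate 1 (adjusted p = 0.0769), −0.03 without GFP replicate 2 (adjusted p = 0.138) and 0.05 without knockdown replicate 3 (adjusted p = 0.486). In the paired fit alone, hypoxia response (median −0.15, camera adjusted p = 0.0216; unpaired 0.122), cell junction and adhesion (−0.09, 0.0302; unpaired 0.0685) and clustered protocadherins (0.15, 0.03; unpaired 0.157) passed. Of the 28 lists 13 passed camera unpaired and 15 paired, and 0 with an estimated correlation in either fit.

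The paired count for Suv39h1 knockdown did not hold with fewer libraries. The 196 genes became 0 without any of the GFP replicates or without knockdown replicate 1 or 3, 92 without knockdown replicate 2 and 64 without all libraries numbered 2. With DESeq2 the paired count was 676. Simulated data with 2-fold changes gave calls for 18.7% of changed genes unpaired and 60.3% paired, with replicate differences set alike in each group as the paired fit assumes.

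The direct comparison of Kdm4d with Suv39h1 knockdown asked whether the manipulations, each aimed at H3K9 methylation, differed (n = 3 and 3). Kdm4d (7.75 ± 0.88), Lyz2 (2.63 ± 0.25, 4.24 ± 0.641 CPM with knockdown), Adam8 (2.41 ± 0.30) and, named after its values were seen, Ncf1 (2.68 ± 0.34) were higher with Kdm4d. These 4 genes rose and 0 fell unpaired, with edgeR adjusted p of 0.00273 to 0.0145 (851 genes at an unadjusted p under 0.05; 83 genes changed with DESeq2). The paired edgeR fit called 123 genes higher and 15 lower with Kdm4d. Among the higher were Cybb, of the phagocyte oxidase (3.35 ± 0.32), the mesothelial genes Lrrn4 (3.65 ± 0.64) and Upk3b (3.11 ± 0.60), the matrix gene Lum (2.19 ± 0.31), Selp (1.18 ± 0.14) and Notch1 (0.64 ± 0.10), and among the lower was Tgfbr1 (−1.07 ± 0.19).

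Of 16 leukocyte markers, 1 was higher with Kdm4d than with knockdown and 15 did not pass unpaired (15 up adjusted over the list alone; median 2.61, camera adjusted p = 1.12e-25, adjusted p = 0.0418 with an estimated correlation). Paired, 13 were higher (15 adjusted over the list alone; median 2.64, camera adjusted p = 9.07e-20), and the call was lost with an estimated correlation (adjusted p = 0.0983). Of 10 mesothelial markers 0 passed unpaired and 2 paired (median 1.15, camera adjusted p = 4.17e-05, adjusted p = 0.334 with an estimated correlation). Cell cycle genes had a median of 0.59 (0 of 37 passing, camera adjusted p = 4.49e-07, adjusted p = 0.519 with an estimated correlation). Fibroblast markers (0.52) and extracellular matrix (0.24) also passed camera, with adjusted p of 0.519 and 0.334 at an estimated correlation. The fibroblast median was 0.04 without Kdm4d replicate 2 (camera adjusted p = 0.397). Inflammation genes had a median of 0.50 (0 of 28 passing, camera adjusted p = 1.34e-05, adjusted p = 0.519 with an estimated correlation), which was −0.25 without Kdm4d replicate 2 (adjusted p = 0.0542). Of the 28 lists 14 passed camera unpaired and 18 paired, and 1 and 0 with an estimated correlation. Those added by pairing were lymphatic endothelial markers (paired adjusted p = 0.000123, unpaired 0.147), interferon response (0.0426 and 0.147), stress and unfolded protein (0.0473 and 0.0837) and clustered protocadherins (0.0332 and 0.109). With an estimated correlation their paired adjusted p was 0.232, 0.731, 0.627 and 0.677 in that order. The unpaired 4 became 1 without any 1 of the knockdown libraries and 8 without Kdm4d replicate 2. Kdm4d and Adam8 lost their calls without knockdown replicate 1 (edgeR adjusted p = 0.132), 2 (0.0622) or 3 (0.094). The paired 138 became 10, 41 and 15 without Kdm4d replicate 1, 2 or 3, 5 without knockdown replicate 1 or 3, and 304 without all libraries numbered 2.

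The overlaps asked whether genes moved by hypoxia moved the other way with either manipulation, in contrasts that share no library. Of the 123 genes lowered by hypoxia, 1 was among the 4 raised with Kdm4d, Lyz2 (0.0323 expected by n1 × n2 / N, Fisher's exact p = 0.0319, Benjamini-Hochberg p = 0.255 over 8 tests). With the paired Kdm4d calls there were 2, Lyz2 and Ccl6 (0.275 expected, Fisher's exact p = 0.0307, adjusted 0.154). Leukocyte markers as a list had a median of −0.76 with hypoxia and 3.28 with Kdm4d, so genes of a shared cell type may make up such overlaps. In the same direction 1 gene was raised in both, Jak3, named after its values were seen (0.453 expected, Fisher's exact p = 0.367, adjusted 0.734). Of the 203 genes raised by hypoxia, 5 were among the 139 lowered with Suv39h1 knockdown in the paired fit, Ankrd37, Hyal1, Lama4, Rin3 and Sgcd, of which Hyal1 and Rin3 were named after their values were seen (1.85 expected, Fisher's exact p = 0.0386, adjusted 0.154). In the same direction, 2 of the 123 lowered genes were among these 139 (1.12 expected, Fisher's exact p = 0.31, adjusted 0.734). With the block in both contrasts, hypoxia has 2 same-numbered pairs and the block draws on the libraries of all groups. There the larger overlap with Suv39h1 knockdown was the one in the same direction, 24 genes lowered in both. The 203 raised genes had a median log2 fold change of 0.11 with Kdm4d and −0.07 with knockdown, where 121 of 203 were lower. The 123 lowered genes had medians of −0.16 and −0.05. These values are across genes, which are not independent replicates.

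The contrasts of Kdm4d and Suv39h1 knockdown with GFP share the GFP libraries, and no gene was called in both, unpaired (4 and 0 calls) or paired (34 and 196 calls). Paired, n1 × n2 / N expected 0.127 genes raised in both and 0.31 raised with Kdm4d and lowered with knockdown. With so few calls, the lack of a shared gene does not show that the manipulations differ. Across genes their log2 fold changes had r = 0.318, where unchanged groups against the same GFP libraries gave a mean of 0.493 (0.474 to 0.521). The covariance of 0.0579 lay above the simulated range of 0.0481 to 0.0557 (mean 0.0511, a difference of 0.0069). Paired, it was 0.0581 against 0.0463 to 0.0537. Since r falls as either contrast varies more across genes, its lower value does not show less sharing. The simulated replicate differences were alike in each group, so the small excess of covariance does not settle a shared effect. GFP libraries also enter the contrast with hypoxia, with the opposite sign. Of the 34 genes lowered in GFP against hypoxia, 3 were among the 4 raised with Kdm4d (Lyz2, Adam8 and Ncf1; 0.00893 expected), and 25 of the 34 raised in the paired fit were among them (0.0759 expected). The correlation was −0.694, against −0.342 in the simulation (covariances −0.155 and −0.0504, a difference of −0.1047). The 3 GFP libraries cannot be split into separate control sets of at least 2, so part of the excess may come from the shared controls. For Suv39h1 knockdown the correlation was −0.227, against −0.349 in the simulation (covariances −0.0533 and −0.0516, a difference of −0.0017).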

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

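The tests of a leukocyte share and of an action of Kdm4d were chosen after the results were seen, and the direct comparison of Kdm4d with Suv39h1 knockdown was planned.

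Leukocyte markers differed between the Kdm4d and Suv39h1 knockdown groups. Their median log2 fold change against GFP was 3.28 with Kdm4d and 0.49 with Suv39h1 knockdown, and in the direct comparison it was 2.61 (camera adjusted p = 1.12e-25, adjusted p = 0.0418 with an estimated correlation; 0.0983 in the paired fit). Mesothelial markers had medians of the same sign, 1.09 with Kdm4d against GFP and 1.15 in the direct comparison, after −1.27 in GFP against hypoxia (camera adjusted p of 1.36e-05, 4.17e-05 and 1.75e-05, and 0.335, 0.334 and 0.417 with an estimated correlation). Both Kdm4d contrasts use the same Kdm4d libraries, and the GFP libraries enter the first and last contrast with opposite sign. The medians are therefore not separate evidence.

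A larger share of leukocytes in the Kdm4d libraries may account for the pattern: the rise over GFP was an even part of the distance from GFP to untransduced hypoxia, with a median of 0.453 over the 16 markers and quartiles of 0.414 and 0.488. The most abundant markers with Kdm4d were Lyz2 (26.2 CPM), Csf1r (21.9 CPM) and Cd68 (21.2 CPM); 3 of the 16 reached 5 CPM in the GFP group, 0 are in another list, and selection with CD31 beads would remove leukocytes that lack CD31. That Kdm4d raised these genes in the cells present stays open, because no cell counts came with the libraries. Most markers above untransduced hypoxia would have spoken for it, and 1 of the 16 lay there. It was Csf1r (21.9 against 20.5 CPM, with 14.1 CPM in GFP, ratio 1.208). Lower levels in the others do not exclude such an action.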

How the results depend on the processing

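Across alternatives 2 values of named genes and 26 of list tests changed direction, and 42 unpaired counts of genes moved by over 1.5 times. Size factors of DESeq2 in edgeR and the stricter filter kept every count within 1.5 times. They also kept every call of the named genes in the 4 contrasts that had unpaired calls, as did DESeq2 and the replicate block. DESeq2 gave 1111 genes for hypoxia, 51 for Kdm4d against GFP, 81 for Suv39h1 knockdown against GFP, 85 for GFP against hypoxia and 83 for Kdm4d against Suv39h1 knockdown. With no filter on low counts the same contrasts gave 179, 14, 1, 48 and 7, and in a fit on the libraries of the contrast alone, with fewer libraries to estimate spread, 34, 0, 0, 1 and 1. The replicate block gave 2789, 34, 196, 89 and 138. Of these, 2789 for hypoxia and 89 for GFP against hypoxia come from contrasts with 2 same-numbered pairs. As hypoxia had no usable library numbered 2, they also take the number 2 difference from the other groups, as if alike in each. All 326 and 34 unpaired calls were among them. With that block in hypoxia, ribosomal protein genes turned to a median of 0.079 (camera adjusted p = 0.534), and endothelial identity (0.03, adjusted p = 0.359) and zinc finger clusters (0.07, adjusted p = 0.269) lost their calls; the block changed no other list call there. For GFP against hypoxia the block raised the lists that passed camera from 7 to 13, with 1 at an estimated correlation in both fits. Lists passing fry in hypoxia rose from 1 to 6 with the block, with 0 at an estimated correlation. An absolute log2 fold change of at least 1 left 215 genes for hypoxia, by fewer genes counted. For these contrasts and others where the count moved, the cause was not tested except where stated.

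Some alternatives were chosen after seeing the data. Without the libraries numbered 2 the counts were 819 for hypoxia, 1 for Kdm4d, 0 for Suv39h1 knockdown, 7 for GFP against hypoxia and 2 for Kdm4d against Suv39h1 knockdown, and ribosomal protein genes in hypoxia turned to 0.11. Without leukocyte-associated genes, those lowered in GFP against hypoxia with the block, 1 remained for Kdm4d against GFP and 1 for Kdm4d against Suv39h1 knockdown. That set holds all 85 genes lowered there, whatever their cell type, and rests on the GFP libraries. The loss of calls for Kdm4d against GFP thus follows in part from how the set was made. The paired counts were 85 for Kdm4d, 676 for Suv39h1 knockdown and 533 for their direct comparison with DESeq2, and 3, 64 and 304 without the libraries numbered 2. Without leukocyte-associated genes the paired Kdm4d count was 4.

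The overlap of hypoxia with Kdm4d in opposite directions was 1 gene, and 6 with DESeq2, 0 in fits of each contrast alone and 9 with the block. With Suv39h1 knockdown it was 0, and 4 with DESeq2 and 23 with the block. With the block in both contrasts, 9 genes lowered in hypoxia were raised with Kdm4d (2.63 expected, Fisher's exact p = 0.000861, adjusted 0.00344 over 8 tests). Of the 34 genes raised with Kdm4d, 30 were also lowered in GFP against hypoxia with the block, Lyz2 and C1qa among them. Such genes may move together with leukocyte content, while Fisher's exact test treats genes as independent. For Suv39h1 knockdown, 24 genes lowered in hypoxia were lowered too (10.8 expected, Fisher's exact p = 0.000171, adjusted 0.00137), and 18 raised in hypoxia were lowered (14.7 expected, Fisher's exact p = 0.334, adjusted 0.891). The hypoxia side of these has 2 same-numbered pairs and takes the number 2 difference from the groups that had such a library. The overlap of Kdm4d with Suv39h1 knockdown was 0, and 1 with DESeq2. The overlap of GFP against hypoxia with Kdm4d was 3, and 48 with DESeq2, 13 with no filter, 0 in fits of each contrast alone, 30 with the block and 1 without the libraries numbered 2. With Suv39h1 knockdown it was 0, and 2 with DESeq2 and 2 with the block.

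Leaving out each library in turn gave 29 to 165 genes for hypoxia, 2 to 11 for Kdm4d, 0 to 0 for Suv39h1 knockdown, 3 to 29 for GFP against hypoxia and 1 to 8 for Kdm4d against Suv39h1 knockdown. Paired, it gave 8 to 27, 0 to 92 and 5 to 170 for the 3 contrasts of transduced groups. The overlaps were 0 to 2 for hypoxia with Kdm4d and 2 to 10 for GFP against hypoxia with Kdm4d. Where hypoxia kept 1 library, it was assumed to vary like the other groups. Of named calls 73 of 195 were kept for hypoxia, 20 of 50 for GFP against hypoxia, 14 of 18 for Kdm4d against GFP and 12 of 18 for Kdm4d against Suv39h1 knockdown. In the unpaired fit the log2 fold change of C3 with Kdm4d ran from −0.0078 (without Kdm4d replicate 2) to 2.44, and that of Angpt2 with Suv39h1 knockdown from −1.50 to 0.21 (without GFP replicate 3).

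List medians that turned had these ranges without single libraries. In hypoxia they were −0.035 to 1.42 for interferon response and −0.61 to 0.13 for ribosomal proteins; in GFP against hypoxia, −0.015 to 1.45 for interferon response. With Kdm4d against GFP they were −0.19 to 0.050 for oxidative phosphorylation, −0.41 to 0.0055 for interferon response, −0.50 to 0.60 for inflammation, −0.41 to 0.044 for stress and −0.45 to 0.22 for ribosomal proteins. With Suv39h1 knockdown they were −0.71 to 0.060 for glycolysis, −0.47 to 0.050 for fibroblast markers and −1.13 to 0.26 for inflammation. Between Kdm4d and Suv39h1 knockdown they were −0.030 to 0.59 for hypoxia response, −0.017 to 0.72 for glycolysis, −0.028 to 0.53 for endothelial identity, −0.023 to 0.24 for junctions, −0.25 to 1.79 for inflammation and −0.048 to 0.74 for ribosomal proteins. The libraries numbered 2 differ in several of these lists, and the cause was not tested. With 10985825 to 13780670 counts per library, genes at low CPM rest on few counts, such as the 6, 1 and 2 counts of Kdm4d with GFP.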

Other observations

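The tests of explanations for the libraries numbered 2 and for the ribosomal protein genes, and the other splits, were chosen after the results were seen, and the gene lists were planned.

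Imprinted genes included large changes with hypoxia. H19, a maternally expressed noncoding RNA, went from 676 ± 248 to 4113 ± 877 CPM (mean ± SD, n = 3 and 2, log2 fold change 2.60 ± 0.43, edgeR adjusted p = 0.0159). Peg3, a paternally expressed zinc finger gene, went from 155 ± 87.9 to 713 ± 217 CPM (2.20 ± 0.39, edgeR adjusted p = 0.0222). The call was lost without normoxia replicate 3 for H19 (2.51, edgeR adjusted p = 0.0534) and without normoxia replicate 1 for Peg3 (2.04, 0.0679). A fit of these libraries alone called neither gene (edgeR adjusted p = 0.0648 and 0.144). Leaving out hypoxia replicate 3 kept 1 hypoxia library, so effect sizes alone are given and no kept call is claimed. The log2 fold changes there were 2.37 for H19 and 1.86 for Peg3. Of 17 imprinted genes 2 rose, 0 fell and 15 did not pass (6 up and 1 down adjusted over the list alone; median 0.41, camera adjusted p = 0.0626). With Suv39h1 knockdown 0 of 17 passed (median 0.13, camera adjusted p = 0.0145, adjusted p = 0.817 with an estimated correlation), and the call was lost without GFP replicate 2 (0.23, adjusted p = 0.145) or knockdown replicate 1 (0.14, adjusted p = 0.106). Zinc finger cluster genes, a class in which many genes carry H3K9 methylation, had small shifts: 3 of 342 rose with hypoxia (0 adjusted over the list alone; median 0.13, camera adjusted p = 0.0244, adjusted p = 0.707 with an estimated correlation), lost without normoxia replicate 2 (0.09, adjusted p = 0.15) or hypoxia replicate 1 (0.02, adjusted p = 0.371), or without all libraries numbered 2 (0.08, adjusted p = 0.218). With Suv39h1 knockdown their median was 0.10 (0 of 342 passing, camera adjusted p = 0.00576, adjusted p = 0.817 with an estimated correlation), lost without GFP replicate 2 (0.06, adjusted p = 0.138) or knockdown replicate 1 (0.04, adjusted p = 0.106).

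In the libraries numbered 2, genes of acute inflammation were high in every group that had one. Cxcl1, a neutrophil chemokine, lay 5.37 log2 units above numbers 1 and 3, Saa3 5.00, Nos2 5.02 and Lcn2 4.24; the genes Nrg1 (−3.57), Mest (−3.33) and Reln (−2.83) lay lower. These genes were chosen after their values were seen.

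A lower share of endothelial cells in the libraries numbered 2, with an even rise of all other cells, is argued against. Markers of the other cells did not rise alike: the highest and lowest medians, of fibroblast (0.77) and cardiomyocyte markers (−0.60), lay 1.37 apart. Between groups the medians ran from 0.45 to 0.98 for fibroblast and from −1.19 to 0.21 for cardiomyocyte markers. The latter were thus not lower in every group. A lower endothelial share with more fibroblasts alone stays open, because the test asked for all other cell types to rise together. The difference followed exonic length (Spearman −0.385) and GC content (0.241) across genes. Such a trend is argued against as the whole source for 2 lists. The inflammation list kept a median of 1.02 after correction (1.01 before) and endothelial identity genes −1.03 (−0.93 before). Fibroblast markers kept theirs as well (0.77 before, 0.84 after). Medians shrank for ribosomal proteins (0.91 to 0.70), stress (0.68 to 0.41) and oxidative phosphorylation (0.33 to 0.16), so a trend may make up part of those. What set these libraries apart, such as a shared day, a batch of cells or an exposure, is not given in the sources used here and stays open.

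The lower ribosomal protein genes with Suv39h1 knockdown were tested against a gene length or GC trend. After the length and GC correction the paired median was −0.42 (−0.44 before), which argues against it as the whole source. An effect of the knockdown may account for the pattern, and so may the hairpin vector itself, since the control carried GFP and no other hairpin was analysed. Spread between libraries stays open as well. Unpaired, the list did not pass camera with an estimated correlation (adjusted p = 0.817) or fry (adjusted p = 0.804). Its unpaired median ran from −0.84 to −0.09 without single libraries. The design does not part these explanations.

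The splits of the 6 libraries of each contrast into 3 and 3 number 10 with the real one, too few for a share under 0.05. For Kdm4d against GFP 1 of 10 splits, the real one, gave as many genes as the real 4 (unpaired) or 34 (paired), and the highest other was 0. For Suv39h1 knockdown against GFP all 10 splits gave as many as the real 0 unpaired, and 1 of 10 as many as the real 196 paired, with 0 as the highest other. For Kdm4d against Suv39h1 knockdown 1 of 10 gave as many as the real 4 or 138, with 0 as the highest other. Of the 10 splits 4 part all same-numbered pairs, the real one among them, and the others of these also gave 0.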
